A study of Rattus norvegicus with 311 samples.

How the data were processed

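Male Sprague Dawley rat hepatocytes were cultured alone or with non-parenchymal cells on collagen-coated multiwell plates and exposed to vehicle or 1 of 4 compounds before sampling on day 1, 3 or 7. RNA was measured with TempO-Seq, a targeted sequencing assay based on ligated detector oligonucleotides. The deposited count matrix, made by the assay's supplier for the authors, holds counts per probe for each well, without normalization. Its values are whole numbers, and each of the 311 columns belongs to a library named in the labels. The submitters' notes name Bowtie, and its version and settings, the genome build and the probe list are not given in the sources used here. It has 22253 probes, of which 237 had no count in any library. Of the probe names, 18278 are a symbol or synonym in the rat gene reference, 468 match after a trailing decimal is removed, and 3507 match none. They give 21108 distinct symbols, of which 1020 have several probes.

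Libraries were grouped by culture, compound, dose and day into 78 groups. The number that names a plate in the library names (1, 3, 5, 7 or 9) was taken as the replicate number. Plate 9 holds 9 libraries of day 3 with gemfibrozil or GW7647 and no vehicle. The labels conflict in places. In monoculture, 33 libraries whose description names phenobarbital carry ketoconazole as compound label, and they were grouped as phenobarbital. As a check, the phenobarbital changes of these libraries were correlated across genes (Spearman) with those of co-culture libraries. With phenobarbital the correlations were 0.681, 0.438 and 0.726 on days 1, 3 and 7, and with ketoconazole 0.449, 0.416 and 0.511, and genes are not independent replicates. For 3 co-culture libraries of day 3 with GW7647 the description gives 0.1 µM and the dose label 1 µM, and they were grouped under 0.1 µM. Phenobarbital doses are given as mM in the protocol and µM in the dose label, and mM was used. No file column or library was left out.

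Counts were analysed in R 4.3.3 with edgeR 4.0.16. For each day 1 fit held the 26 groups, and a separate fit held the 6 vehicle groups for comparisons over time. Genes passed filterByExpr with a minimum count of 10, which left 12504, 13439 and 13707 on days 1, 3 and 7 and 11823 in the vehicle fit. Libraries were scaled by TMM, and the quasi-likelihood test (estimateDisp with a trend, glmQLFit, glmQLFTest) was two-sided with Benjamini-Hochberg adjustment over the genes of each comparison and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the root of F. Means and SDs are of CPM on TMM-scaled libraries, and log2 CPM used a prior count of 2. The comparisons were co-culture against monoculture in vehicle, days 3 and 7 against day 1 in vehicle, each dose against the vehicle of its day and culture, GW7647 against gemfibrozil directly, and the difference of each response between cultures. Comparisons with the same vehicle libraries are not independent.

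Gene lists were written before the data were examined, as were the comparisons, the tests and most alternatives. The 21 lists are hepatocyte functions, stellate and mesenchymal, macrophage, endothelial, cholangiocyte and progenitor, lymphocyte, and neutrophil and erythroid markers, targets of CAR and PXR, PPAR-alpha, the aryl hydrocarbon receptor, NRF2 and p53, genes of cholesterol synthesis, fatty acid synthesis, stress (the integrated stress and unfolded protein responses), cytoskeleton, cell cycle, inflammation, bile acids and reference, and mitochondrially encoded genes, for which 0 of 9 have a probe. Cyp2b1, Actb, B2m, Angptl4, Cyp4a3 and Hsd17b4 have no probe of that name and are not analysed here. Lists were tested with fry of limma 3.58.1 on log2 CPM, with Benjamini-Hochberg adjustment over the lists of a comparison, and the count adjusted over the list alone corrects the edgeR p-values over its members. A list score is the mean log2 CPM of the members minus that of the vehicle libraries of the same culture and day.

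Genes to name were chosen by a rule fixed before the data were examined. Candidates had an adjusted p under 0.05, groups that do not overlap and a mean of at least 10 CPM in 1 group. From them came the 8 highest and 8 lowest changes by culture on day 7, the 6 highest and 6 lowest by time and by compound on day 7, the 4 smallest p-values for each difference of response on day 7, up to 6 members of each list with the smallest p, and 12 genes of known relevance. Some of these genes are not reported here. Where all libraries of a group had 0 counts, a fold change is a lower bound against 3 counts over the group. Where a group had 1 to 3 counts, the ratio has an exact 95% interval. Both cover counting error only. Pairing by plate was checked: on days 1, 3 and 7 the residuals of libraries of the same plate had mean correlations of 0.287, 0.238 and 0.328, and those of other plates -0.094, -0.063 and -0.109. Plate as a block is an alternative, as the main test was fixed without it.

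The alternatives were DESeq2 1.42.0 with its Wald test, DESeq2's size factors in the edgeR fit, no filter, plate as a block, only the groups compared in a fit, libraries of at least 500000 counts, the dose label for the 3 conflicting libraries, probes of a symbol summed, and each plate left out. Added later were a covariate for library complexity (probes detected after thinning), a fit without the 2 libraries of fewest counts and a fit without 2 libraries out of place for their label. Other splits of the libraries of a comparison were tested with limma-trend, up to 100 each. The median SD between libraries of a group was 0.536, 0.612 and 0.631 on the log2 scale on days 1, 3 and 7. Data simulated for phenobarbital against vehicle of day 7 in monoculture tested the steps. There edgeR called 3% of genes changed by 1 and 42% of those changed by 2 on the log2 scale, with 1 unchanged gene called. In 2-group fits DESeq2 called 9% and 55% with 58, limma-trend 0% and 5% with 0. On those data fry gave p-values of 1.21e-05 and 4.09e-07 for lists made to rise and fall and 0.683 for an unchanged list. Values were read with version 1.17.8 of data.table, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.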

Results

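Transcripts were measured in 311 libraries of primary hepatocytes from male Sprague Dawley rats. The hepatocytes were cultured alone in 156 libraries (monoculture) and together with non-parenchymal liver cells in 155 libraries (co-culture). The assay, TempO-Seq, counts detector oligonucleotides ligated on their transcripts, so values exist for targeted genes alone. For the day before sampling on day 1, 3 or 7 after plating, the cells received vehicle or 1 of 4 compounds at 3 doses each. Phenobarbital is a classical activator of the nuclear receptor CAR, GW7647 and gemfibrozil activate the lipid sensor PPAR-alpha, and ketoconazole is an azole antifungal that inhibits cytochrome P450 enzymes, including the sterol demethylase Cyp51. The groups number 78, of which 65 hold 4 libraries, 7 hold 3 and 6 hold 5. Library totals ran from 412414 to 12272575 counts with a median of 6054414. The labels speak of biological replicates without saying that they came from separate animals, so the p-values measure the spread between these libraries, which may be technical. Changes are log2 fold changes ± the standard error of edgeR's quasi-likelihood estimate, and adjusted p-values are Benjamini-Hochberg values over all genes of the comparison unless a list is named, with fry p-values adjusted over the lists. The rotation test fry asks whether the genes of a list move on balance one way, and compares them with no other genes. Counts without a plate refer to the same fit with all libraries of that plate left out, and the size of a list to its measured members.

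The first comparison asked what non-parenchymal cells add to the profile of vehicle-treated wells. The macrophage gene Lyz2, which encodes a lysozyme, averaged 15.8 ± 16.2 CPM (SD, n = 4) in co-culture and 3.14 ± 2.72 CPM (SD, n = 4) in monoculture on day 1, 144 ± 75.5 and 24.4 ± 21.3 CPM on day 3, and 787 ± 373 and 234 ± 98.8 CPM on day 7. On days 3 and 7 the 4 co-culture libraries lay above the 4 monoculture libraries, yet the edgeR adjusted p for Lyz2 was 1 on each day. No list of cell type markers passed either. On day 7 the 20 measured endothelial markers had a median difference of 2.10 and the 21 macrophage markers one of 1.03, with 20 and 20 members above 0, 0 and 0 of them past the edgeR threshold, and a fry p of 0.902 each. edgeR called 0 genes on each day, against 113, 492 and 60 at an unadjusted p under 0.05 on days 1, 3 and 7, and DESeq2 called 10, 66 and 3.

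Time in culture was compared within vehicle wells. Between day 1 and day 7 the hepatocyte genes Cyp3a2 and Cyp2e1, cytochrome P450 enzymes, and Apoa2, an apolipoprotein, fell steeply. Cyp3a2 changed by -8.85 ± 0.73 in monoculture and -9.60 ± 0.76 in co-culture (n = 4 per group, edgeR adjusted p 3.18e-08 and 1.78e-08), from 248 to 0.533 CPM and from 320 to 0.405 CPM, and the co-culture day 1 mean includes 1 library at 661.6 CPM, far from the others. Cyp2e1 changed by -5.73 ± 0.70 and -6.36 ± 0.73, and Apoa2 by -8.67 ± 0.76 and -8.43 ± 0.74. Albumin (Alb) changed less, by -1.81 ± 0.51 in co-culture (edgeR adjusted p 0.0138), and its change of -1.30 ± 0.51 in monoculture did not pass (0.0652, and 0.0122 with plate as a block). Of hepatocyte functions, 1 of 47 rose and 18 fell (1 and 21 adjusted over the list alone, median -1.08, fry p 0.00188; 17, 17, 11 and 14 falling without plates 1, 3, 5 and 7) in monoculture. In co-culture, 19 of 47 fell (25 over the list alone, median -1.58, fry p 0.00143). Among targets of the drug-sensing receptors CAR and PXR, 1 of 22 rose and 6 fell (1 and 8 over the list alone, fry p 2.17e-04, 0 and 9 with the block) in monoculture. For co-culture, 1 of 22 rose and 8 fell (1 and 9 over the list alone, fry p 7.63e-05, 0 and 9 with the block).

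Over the same days, collagen and other mesenchymal genes rose in both cultures. Col3a1, a fibrillar collagen chain, changed by 7.68 ± 1.10 in monoculture, from 12.1 to 2490 CPM, and by 8.37 ± 1.14 in co-culture, from 13.3 to 4401 CPM (n = 4 per group, edgeR adjusted p 4.75e-05 and 2.26e-05). Col1a2, Loxl1, which cross-links matrix, and Mgp, a matrix protein, changed by 7.27 ± 1.11, 7.33 ± 0.72 and 7.52 ± 1.07 in monoculture. Of stellate and mesenchymal markers, 20 of 23 rose (22 over the list alone, median 5.84, fry p 1.54e-06) in monoculture. In co-culture, 21 of 23 rose (21 over the list alone, median 6.44, fry p 2.14e-07). Vim and Lgals1, both abundant in mesenchymal cells and in dedifferentiating hepatocytes, rose by 4.94 ± 0.68 and 4.86 ± 0.91 in monoculture and by 5.49 ± 0.69 and 5.26 ± 0.93 in co-culture. The biliary transcription factor Sox9 rose by 4.83 ± 0.74 and 4.38 ± 0.72, and the progenitor marker Prom1 by 4.14 ± 0.58 and 5.14 ± 0.63. Of the cholangiocyte and progenitor list, 6 of 9 rose (6 over the list alone, median 4.01, fry p 3.08e-08) in monoculture. In co-culture, 6 of 9 rose (7 over the list alone, fry p 9.62e-09). With members of 0 counts in a group at their lower bound the monoculture median is 3.81, and no other list median given here moves.

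**Figure D1:**
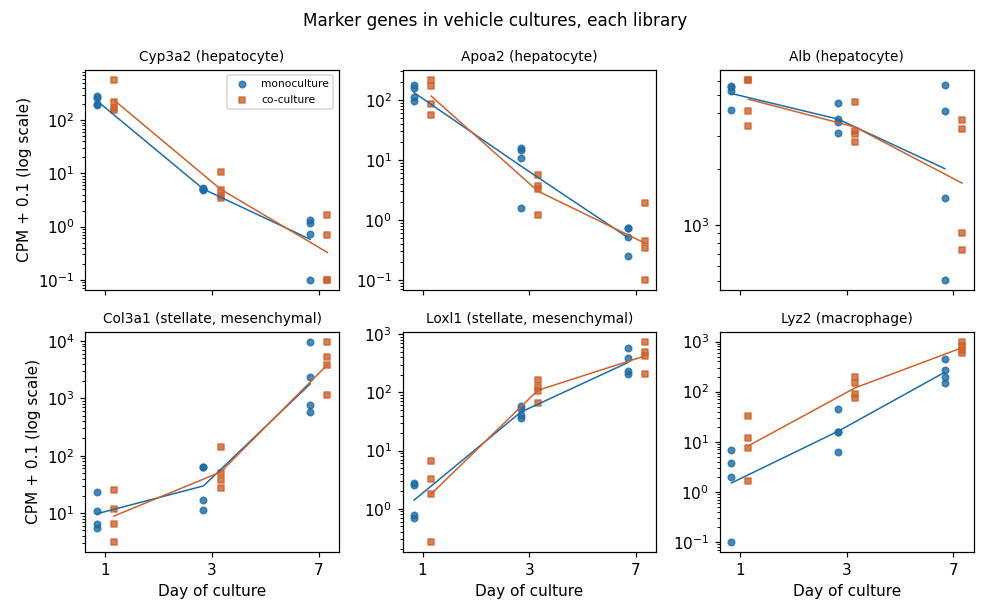
CPM of selected genes in vehicle wells on days 1, 3 and 7, on a log axis, with 1 point per library and a line through the group means of the log values for monoculture and co-culture. Scaled by library totals alone, the monoculture points of Col3a1 lie between 5.37 and 23.0 CPM on day 1 and between 584 and 9586 CPM on day 7, and those of Cyp3a2 between 191 and 290 and between 0 and 1.24 CPM.

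Macrophage markers moved in both directions between days 1 and 7. Lyz2 rose by 6.01 ± 0.88 in monoculture and 5.45 ± 0.85 in co-culture (edgeR adjusted p 5.78e-05 and 9.14e-05, n = 4 per group), the mannose receptor Mrc1, shared with endothelial cells, by 4.17 ± 0.55 and 4.26 ± 0.54, the scavenger receptor Cd163 by 2.84 ± 0.54 and 3.23 ± 0.55, and the complement gene C1qc by 1.95 ± 0.52 and 2.64 ± 0.53. Cd5l, a protein secreted by macrophages, changed by -3.17 ± 0.92 in monoculture. In the macrophage list, 6 of 20 rose and 1 fell (8 and 1 over the list alone, median 1.23, fry p 0.00788; 7, 3, 3 and 4 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 10 of 20 rose and 2 fell (13 and 2 over the list alone, median 2.27, fry p 7.63e-05; 11, 5, 7 and 6 rising without plates 1, 3, 5 and 7). Of endothelial markers, 3 of 18 rose (3 over the list alone, median -1.12, mean -0.46, direction of fry up, fry p 0.999; 1, 1, 1 and 2 rising without plates 1, 3, 5 and 7) in monoculture, where the test differs in sign from the median and the mean. In co-culture, 3 of 18 rose (3 over the list alone, median 0.98, fry p 0.307). Of the neutrophil and erythroid list 1 of 2 rose (2 over the list alone, fry p 2.17e-04) in monoculture. For co-culture, 1 of 2 rose (2 over the list alone, fry p 3.29e-05).

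Targets of NRF2, the regulator of antioxidant genes, were lower with time. Among them 7 of 18 fell (8 over the list alone, fry p 0.00743) in monoculture, with Gsr at -1.65 ± 0.34 and Gclc, the rate-limiting enzyme of glutathione synthesis, at -1.27 ± 0.33. In co-culture, 5 of 18 fell (5 over the list alone, fry p 0.021, 9 falling with the block). The lipid genes of the PPAR-alpha list went both ways, since Lpl, Cd36 and Ucp2 rose by 4.55 ± 0.85, 3.13 ± 0.76 and 4.40 ± 0.65 in monoculture while the lipid droplet gene Plin2 changed by -1.78 ± 0.31 (edgeR adjusted p 6.45e-04, 0.00543, 5.78e-05 and 3.57e-04). Cell cycle genes rose in part, with Ccnb2, a mitotic cyclin, at 2.20 ± 0.62 in monoculture and 2.43 ± 0.62 in co-culture. Of the list, 3 of 24 rose (2 over the list alone, fry p 0.11) in monoculture. For co-culture, 7 of 24 rose (8 over the list alone, fry p 0.0252). Of genes often used as references, 4 of 9 fell (4 over the list alone, fry p 0.00321) in monoculture, with Pgk1 at -2.33 ± 0.36 and Gapdh at -1.52 ± 0.35. In co-culture, 2 of 9 fell (2 over the list alone, fry p 0.00936, 5 falling with the block). Targets of the aryl hydrocarbon receptor, p53 targets, inflammation genes, stress genes, bile acid genes, fatty acid synthesis genes and cytoskeletal genes had medians of 1.05, -0.10, -0.41, -0.16, 0.23, -0.03 and 0.23 in monoculture, and none of these lists passed (fry p 0.747, 0.476, 0.11, 0.106, 0.961, 0.961 and 0.663). The mean and the median differ in sign for p53 targets (0.25), bile acid genes (-0.24) and fatty acid synthesis genes (0.23). Of cholesterol synthesis genes, 2 of 21 fell (2 over the list alone, fry p 0.0473, 0.0609 with the block) in co-culture.

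The genes with the largest changes that passed in both cultures included several that were near absent on day 1. Prl8a2, a member of the prolactin family, rose from 0.0323 to 357 CPM in monoculture, a ratio of 13500 (2420 to 532000) by its counting interval, and from 0.0743 to 537 CPM in co-culture. Col1a1 had 0 counts on day 1 and was at least 206-fold higher on day 7 in monoculture and at least 322-fold higher in co-culture, against a floor of 3 counts over the group. Ndst3, a heparan sulphate enzyme, was at least 599-fold and 501-fold higher against that floor. The guidance factor Slit3 was at least 577-fold higher in monoculture, and cardiac troponin T (Tnnt2) and the vesicle protein Sv2c rose by ratios of 2050 (567 to 16900) and 5100 (915 to 202000). In monoculture 1 library held most of the day 7 counts of each of these 6 genes, and without it the bounds were 108, 290 and 331 for Col1a1, Ndst3 and Slit3. Among those that fell, Serpina3c was at least 155-fold lower (24.1-fold without the library that holds 577 of its 656 day 1 counts) and LOC100360095 at least 205-fold lower in monoculture, and Rup2 changed by -9.54 ± 0.77. Across all genes edgeR called 2653 in monoculture (1618 higher, 1035 lower) and 2695 in co-culture (1801 higher, 894 lower) of 11823 tested. With library complexity as a covariate the counts were 1125 and 1393, and leaving out plates 1, 3, 5 and 7 gave 1834, 1939, 891 and 1893 in monoculture and 1923, 1086, 1848 and 2038 in co-culture. Leaving out 1 plate lost the monoculture calls of C1qc without plate 3 or 5 (0.105), of Gapdh and Gclc without plate 5 (0.0647), of Ccnb2 without plate 5 or 7 (0.171) and of Cd5l and Cd36 without plate 7 (0.0537), with the highest edgeR adjusted p in parentheses. The co-culture calls lost were those of Gsr and Gclc without plate 3 (0.052), of Ccnb2 without plate 5 (0.0867) and of Alb without plate 7 (0.0528).

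By day 3 part of this shift was present. Cyp3a2 had changed by -5.38 ± 0.60 in monoculture and -5.65 ± 0.61 in co-culture and Cyp2e1 by -5.02 ± 0.68 and -6.33 ± 0.74 (n = 4 per group, edgeR adjusted p 3.82e-05, 1.61e-05, 2.83e-04 and 1.77e-05). Loxl1 rose by 5.03 ± 0.66 and 5.32 ± 0.66, Sox9 by 4.35 ± 0.72 and 4.05 ± 0.71, and Vim by 2.97 ± 0.62 and 3.54 ± 0.64. Insig1, a sterol sensor, changed by -2.88 ± 0.45 and -3.42 ± 0.47, and the haem oxygenase Hmox1 by -3.41 ± 0.75 and -3.65 ± 0.77. Lyz2 rose by 3.04 ± 0.80 and 3.34 ± 0.77, whereas Cd68, another macrophage gene, changed by -4.41 ± 0.86 in co-culture (edgeR adjusted p 0.00283) and stood at -2.49 ± 0.72 in monoculture (0.0633, and 0.0205 with plate as a block). Of stellate and mesenchymal markers, 2 of 23 rose (8 over the list alone, fry p 0.06, 0.00343 with the block) in monoculture. For co-culture, 6 of 23 rose (13 over the list alone, fry p 0.0156, 12 rising with the block). edgeR called 298 genes in monoculture (577 with plate as a block) and 1071 in co-culture (1625 with the block), and without plates 1, 3, 5 and 7 it called 206, 60, 61 and 42 and 1192, 229, 159 and 373. Calls lost in monoculture with 1 plate left out were those of Lyz2 without plate 1, 3, 5 or 7 (0.177), of Hmox1 without plate 3, 5 or 7 (0.16) and of Vim without plate 5 or 7 (0.125). Among co-culture calls, those lost were of Lyz2 without plate 3, 5 or 7 (0.0697) and of Hmox1 without plate 5 or 7 (0.0614).

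The co-culture change from day 1 to day 7 minus the monoculture change had 0 genes past the edgeR threshold, with 34 at an unadjusted p under 0.05 and 0 by DESeq2. For the stellate and mesenchymal list the median of this difference was 0.60 (fry p 0.951), for the macrophage list 0.82 (0.951) and for the endothelial list 1.59, with 18 of 18 members above 0 (0.951).

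Phenobarbital at 10 mM, compared with vehicle on the same day, addressed CAR activation. On day 1 its best known targets were higher in monoculture. Cyp2b2, the classical phenobarbital-inducible cytochrome P450, changed by 6.67 ± 1.65, from 0.28 to 29.1 ± 47.1 CPM (SD, n = 4), the glucuronosyltransferase Ugt2b1 by 3.49 ± 0.78, and Cyp3a23/3a1 by 2.75 ± 0.86 (edgeR adjusted p 0.00843, 0.00272 and 0.0479). The Cyp2b2 mean rests largely on 1 library at 98.86 CPM. In co-culture Ugt2b1 rose by 2.93 ± 0.76, while Cyp2b2 at 4.27 ± 1.45 and Cyp3a23/3a1 at 2.61 ± 0.86 did not pass (adjusted p 0.0867 and 0.0774, and 0.0291 for the second with plate as a block). In the list of CAR and PXR targets, 3 of 24 rose (3 over the list alone, median 0.77, fry p 0.324; 0, 2, 2 and 2 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 2 of 24 rose (4 over the list alone, fry p 0.698). The mitochondrial lipid genes Acot2 and Pdk4, PPAR-alpha targets, rose by 2.55 ± 0.49 and 5.31 ± 1.30 in monoculture and by 1.85 ± 0.48 and 5.91 ± 1.35 in co-culture.

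The wider day 1 response to phenobarbital held stress genes going up and cytoskeletal genes going down. The stress transcription factor Ddit3 rose by 5.29 ± 1.08 in monoculture and 5.38 ± 1.09 in co-culture (n = 4 per group, edgeR adjusted p 0.00113 and 0.0017), with 1 monoculture library at 9369 CPM far above the rest. The pseudokinase Trib3 rose by 2.58 ± 0.48 and 2.40 ± 0.47, the stress hormone Gdf15 by 3.31 ± 0.75 and 3.42 ± 0.76, and Atf4, which drives the integrated stress response, by 1.67 ± 0.33 and 1.32 ± 0.33. Of stress genes, 12 of 26 rose (16 over the list alone, median 1.43, fry p 0.00989; 9, 10, 4 and 3 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 10 of 26 rose (15 over the list alone, median 1.15, fry p 0.00277; 7, 10, 1 and 1 rising without plates 1, 3, 5 and 7). Tropomyosin (Tpm1) changed by -4.77 ± 0.94 and -3.80 ± 0.90, the actin cross-linker Actn1 by -2.37 ± 0.42 and -1.65 ± 0.41, and keratin Krt8 by -2.28 ± 0.49 and -1.99 ± 0.48. Of cytoskeletal genes, 11 of 27 fell (19 over the list alone, median -1.81, fry p 4.92e-07; 8, 7, 6 and 8 falling without plates 1, 3, 5 and 7) in monoculture. For co-culture, 7 of 27 fell (16 over the list alone, fry p 4.23e-05, 12 falling with the block). Sox9 changed by -4.14 ± 1.02 in monoculture and stood at -2.88 ± 0.95 in co-culture (adjusted p 0.0767, and 0.00805 with plate as a block). Of stellate and mesenchymal markers, 2 of 18 fell (3 over the list alone, fry p 0.0372, 5 falling with the block) in monoculture. In co-culture, 3 of 18 fell (4 over the list alone, fry p 0.0309, 5 falling with the block).

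The plates differed in these day 1 responses. As the mean log2 difference from vehicle over a list, the PPAR-alpha score with phenobarbital 10 mM was 1.47, 1.47, -0.10 and -0.62 on plates 1, 3, 5 and 7 in monoculture and 1.15, 0.84, -0.11 and -0.78 in co-culture. The stress score on those plates was 0.06, 0.25, 1.39 and 1.92 in monoculture and 0.63, 0.15, 1.56 and 1.92 in co-culture. edgeR called 541 genes in monoculture (241 higher, 300 lower, 927 with plate as a block, 18 in a 2-group fit) and 351 in co-culture (171 higher, 180 lower, 859 with the block, 341 in that fit). The fits without plates 1, 3, 5 and 7 called 447, 430, 104 and 180 in monoculture and 154, 190, 52 and 55 in co-culture. With 1 plate left out, the monoculture calls lost were those of Ugt2b1 and Cyp2b2 (3.88 there) without plate 1 (0.209), of Cyp3a23/3a1 without plate 1, 3, 5 or 7 (0.288), of Sox9 without plate 3 (0.0678), of Pdk4 without plate 5 or 7 (0.135) and of Ddit3 and Gdf15 without plate 7 (0.346), where they stood at 3.24 and 1.68. Lost in co-culture were those of Krt8 and Acot2 without plate 1, 3 or 5 (0.181), of Ugt2b1 without plate 1, 3 or 7 (0.185), of Tpm1 and Actn1 without plate 1, 5 or 7 (0.124), of Trib3 without plate 5 (0.0945), of Ddit3, Gdf15 and Atf4 without plate 5 or 7 (0.284), with Ddit3 at 3.66 and Gdf15 at 2.34 without plate 7, and of Pdk4 without plate 7 (0.178).

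On day 3 phenobarbital 10 mM again raised stress genes and lowered cytoskeletal and mesenchymal ones (n = 3 treated, 4 vehicle libraries). Ddit3 rose by 3.99 ± 0.79 in monoculture and 3.34 ± 0.77 in co-culture and Trib3 by 2.45 ± 0.45 and 2.15 ± 0.45 (edgeR adjusted p 0.00134, 0.00719, 5.36e-04 and 0.00391). Slc7a11, the cystine importer that feeds glutathione synthesis, rose by 5.97 ± 1.27 and 4.33 ± 1.16, and the oxidative stress gene Osgin1 by 1.65 ± 0.43 and 1.49 ± 0.43. The smooth muscle gene Cnn1 changed by -3.42 ± 0.93 and -4.49 ± 0.99, Tpm1 changed by -3.42 ± 0.85 in monoculture, and Sox9 changed by -5.41 ± 1.37 in monoculture against -4.07 ± 1.28 in co-culture (adjusted p 0.0556, and 6.17e-05 with plate as a block). C1qc changed by -4.03 ± 1.09 in co-culture and stood at -2.96 ± 1.03 in monoculture (adjusted p 0.114, and 7.09e-04 with the block). Of stress genes, 5 of 26 rose (12 over the list alone, median 1.14, fry p 1.8e-04, 13 rising with the block; 1, 4, 3 and 4 rising without plates 1, 3, 5 and 7) in monoculture. For co-culture, 3 of 26 rose (13 over the list alone, fry p 2.25e-04, 16 rising with the block). Of NRF2 targets, 3 of 19 rose and 0 fell (4 and 1 over the list alone, fry p 0.00255, 5 and 1 with the block) in monoculture. In co-culture, 2 of 19 rose and 1 fell (4 and 2 over the list alone, fry p 0.0218, 8 and 2 with the block). Of stellate and mesenchymal markers, 0 of 21 rose and 3 fell (1 and 5 over the list alone, fry p 0.0328, 0 and 7 with the block) in monoculture. For co-culture, 4 of 21 fell (6 over the list alone, fry p 0.00198, 11 falling with the block). Of cytoskeletal genes, 5 of 28 fell (18 over the list alone, fry p 2.07e-04, 14 falling with the block) in monoculture. In co-culture, 7 of 28 fell (13 over the list alone, fry p 9.53e-05, 16 falling with the block). edgeR called 352 genes in monoculture (1124 with plate as a block, 1019 in a 2-group fit) and 441 in co-culture (2399 and 819), and without plates 1, 3, 5 and 7 it called 40, 236, 44 and 36 and 60, 422, 39 and 12. The median of all genes in co-culture was 0.34, and 0.46 with DESeq2's size factors, so changes there are relative to that shift. Leaving out 1 plate lost the monoculture calls of Ddit3 without plate 1 (0.0527), of Cnn1 without plate 1, 3, 5 or 7 (0.245), of Tpm1 and Sox9 without plate 1, 5 or 7 (0.295), of Osgin1 without plate 3, 5 or 7 (0.323) and of Slc7a11 without plate 5 or 7 (0.143). The co-culture calls lost were those of Osgin1 without plate 1, 3, 5 or 7 (0.231), of Ddit3 without plate 1 or 5 (0.0782), of Slc7a11 and C1qc without plate 1, 5 or 7 (0.278), of Cnn1 without plate 1 or 7 (0.113) and of Trib3 without plate 5 (0.0658).

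On day 7 the genes that rose with phenobarbital 10 mM included some of glutathione metabolism (n = 4 per group). The glutathione transferases Gsta2 and Gsta5 rose by 5.00 ± 0.89 and 4.71 ± 0.88 in monoculture and by 4.74 ± 0.88 and 4.57 ± 0.88 in co-culture (edgeR adjusted p 0.00139, 0.00158, 0.00869 and 0.00869). Slc7a11 rose by 3.96 ± 0.96 and 4.79 ± 1.00, and Gclc rose by 2.13 ± 0.45 in monoculture against 1.91 ± 0.45 in co-culture (adjusted p 0.056, and 0.00111 with plate as a block). Of NRF2 targets, 3 of 19 rose and 0 fell (14 and 1 over the list alone, fry p 0.00262, 8 and 1 with the block) in monoculture. In co-culture, 1 of 19 rose (4 over the list alone, fry p 0.0187, 4 rising with the block). Ddit3, Trib3 and the chaperone Hspa5 rose by 4.66 ± 1.04, 3.44 ± 0.88 and 3.01 ± 0.69 in monoculture, and stood at 4.47 ± 1.04, 3.25 ± 0.87 and 2.90 ± 0.69 in co-culture (adjusted p 0.056, 0.142 and 0.0589, and 0.0106, 0.00111 and 0.0153 with the block). Of stress genes, 4 of 26 rose (7 over the list alone, median 1.13, fry p 0.0105, 8 rising with the block; 6, 0, 0 and 0 rising without plates 1, 3, 5 and 7) in monoculture. For co-culture, 0 of 26 rose (10 over the list alone, fry p 0.0187). Tpm1 changed by -3.09 ± 0.70 in monoculture and stood at -1.84 ± 0.67 in co-culture (adjusted p 0.456). The plates differed again, with PPAR-alpha scores of 0.64, 0.32, -0.86 and -0.81 on plates 1, 3, 5 and 7 in monoculture and 0.24, 0.15, -0.84 and -0.28 in co-culture. The CAR and PXR targets had a median of 0.68 in monoculture and 0.39 in co-culture with 0 members past the edgeR threshold. edgeR called 168 genes in monoculture (668 with the block, 2 in a 2-group fit) and 3 in co-culture (84 and 0, 41 by DESeq2), Gsta2, Gsta5 and Slc7a11 being those of co-culture. Without plates 1, 3, 5 and 7 it called 359, 1, 13 and 0 and 154, 0, 0 and 0. Calls lost in monoculture with 1 plate left out were those of Ddit3, Trib3, Tpm1, Slc7a11, Gclc, Gsta5 and Hspa5 without plate 3, 5 or 7 (0.589), with Ddit3 at 2.82 and Hspa5 at 2.19 without plate 3, and of Gsta2 without plate 3 or 7 (0.0823). Among co-culture calls, those lost were of Slc7a11, Gsta2 and Gsta5 without plate 3, 5 or 7 (1).

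GW7647 at 1 µM, a potent PPAR-alpha agonist, raised genes of fatty acid oxidation on day 1. Ech1, an enzyme of peroxisomal and mitochondrial beta-oxidation, rose by 2.98 ± 0.50 in monoculture and by 2.45 ± 0.49 in co-culture (n = 4 per group, edgeR adjusted p 6.65e-04 and 0.0207). The acyl-CoA thioesterase Acot2 rose by 2.69 ± 0.49 and 2.17 ± 0.48, and Cpt1b, which imports fatty acids into mitochondria, by 4.38 ± 0.90 and 4.50 ± 0.92. Of PPAR-alpha targets, 10 of 45 rose (35 over the list alone, median 1.85, fry p 7.23e-06, 19 rising with the block; 0, 0, 2 and 8 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 7 of 45 rose (30 over the list alone, median 1.33, fry p 0.00115, 16 rising with the block; 0, 1, 1 and 6 rising without plates 1, 3, 5 and 7). edgeR called 14 genes in monoculture, all higher (30 with plate as a block), and 15 in co-culture (10 higher, 5 lower, 88 with the block). The fits without plates 1, 3, 5 and 7 called 0, 0, 2 and 11 and 0, 1, 1 and 25. With 1 plate left out, the monoculture calls lost were those of Ech1 without plate 1 or 3 (0.117) and of Acot2 and Cpt1b without plate 1, 3 or 5 (0.343). Lost in co-culture were those of Ech1 without plate 1 or 3 (0.551), of Acot2 without plate 1, 3 or 5 (0.622) and of Cpt1b without plate 1 or 5 (0.551).

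On day 3 the lipid carrier Fabp1, the acyl-CoA synthetase Acsl1 and the peroxisomal enzyme Ehhadh rose in monoculture with GW7647 1 µM, by 6.31 ± 1.10, 2.24 ± 0.42 and 6.06 ± 1.26 (n = 4 treated, 4 vehicle, edgeR adjusted p 0.00178, 0.00346 and 0.0114). In co-culture they stood at 4.67 ± 1.01, 1.68 ± 0.40 and 4.72 ± 1.19 (n = 5 treated, 4 vehicle, adjusted p 0.19, 0.212 and 0.279, and 0.0417 for Fabp1 with plate as a block). Of PPAR-alpha targets, 9 of 45 rose (28 over the list alone, median 2.13, fry p 2.39e-07; 1, 3, 3, 0 and 8 rising without plates 1, 3, 5, 7 and 9) in monoculture. In co-culture, 0 of 45 rose (15 over the list alone, median 1.22, fry p 0.00603, 2 rising with the block). The co-culture library of plate 3 labelled 1 µM had a PPAR-alpha score of -0.45, against 1.42 to 2.27 in the other 4 libraries of its group. Without it and that plate's gemfibrozil 100 µM library, edgeR called Acsl1 and Fabp1 (adjusted p 0.0252 each). Then 19 members rose over the list alone (median 1.40, fry p 1.86e-05). Leaving out a low score favours a rise. edgeR called 13 genes in monoculture (26 with the block, 23 with DESeq2's size factors) and 0 in co-culture, where 1368 had an unadjusted p under 0.05, 168 passed by DESeq2 and 2 with the block. Without plates 1, 3, 5, 7 and 9 it called 1, 5, 6, 0 and 12 in monoculture and 0, 1, 0, 0 and 0 in co-culture. Leaving out 1 plate lost the monoculture calls of Ehhadh without plate 1, 3 or 7 (0.296), of Acsl1 without plate 1 or 7 (0.576) and of Fabp1 without plate 7 (0.0771). DESeq2's size factors moved the median of all genes from 0.05 to 0.26 in monoculture and from 0.13 to 0.25 in co-culture.

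On day 7 no gene passed with GW7647 1 µM (n = 4 per group). edgeR called 0 in both cultures, with 312 and 191 at an unadjusted p under 0.05 (fewer than by chance), 5 and 3 by DESeq2, and 1 and 0 with plate as a block. Fabp1 stood at 6.89 ± 1.76 in monoculture (0.0279 adjusted p with the block, 0.637 without) and 4.24 ± 1.56 in co-culture, and the fatty acid hydroxylase Cyp4a1 at 3.56 ± 1.33 and 3.32 ± 1.32. As a list the PPAR-alpha targets passed in monoculture, where 0 of 46 rose (30 over the list alone, median 1.71, fry p 0.0409, 1 rising with the block), and not in co-culture, where 0 of 46 rose (0 over the list alone, fry p 0.955).

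**Figure D2:**
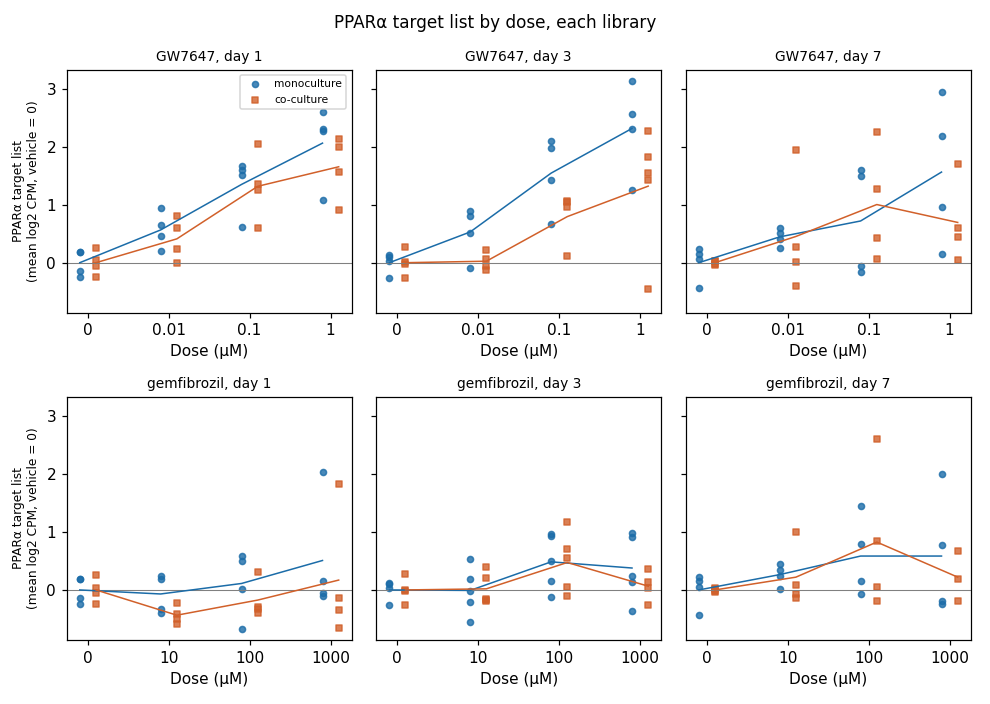
PPAR-alpha score of each library (mean log2 difference from the vehicle mean of its culture and day over the list's genes), by dose of GW7647 and gemfibrozil, culture and day, with 1 point per library and a line through the group means. On day 1 the plate 3 library with gemfibrozil 1000 µM in monoculture stands at 2.04, and the libraries of the other 3 plates lie between -0.10 and 0.15.

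Gemfibrozil at 1000 µM, a fibrate drug, raised stress genes and some PPAR-alpha targets on day 1, with the list scores high on different plates. Acot2 rose by 3.39 ± 0.51 in monoculture and by 3.04 ± 0.50 in co-culture, and by 3.20 and 2.41 without plate 3 (n = 4 per group, edgeR adjusted p 2.66e-05 and 3.85e-04). Pdk4, a brake on glucose oxidation, rose by 6.29 ± 1.35 and 5.90 ± 1.35, and Cyp4a1 by 4.75 ± 1.06 and 3.65 ± 1.01, the latter with an adjusted p of 0.0336 and of 0.0517 with plate as a block. The PPAR-alpha score was 2.04 and 1.83 on plate 3 in monoculture and co-culture, and at most 0.15 in the 6 libraries of the other plates. Without plate 3, Pdk4 stood at 3.65 and 3.86 and Cyp4a1 at 0.87 ± 0.75 and -1.37 ± 0.79. Of PPAR-alpha targets, 9 of 45 rose (13 over the list alone, median 0.66, fry p 0.276; 1, 1, 1 and 9 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 5 of 45 rose (11 over the list alone, median 0.34, fry p 0.741; 0, 2, 1 and 8 rising without plates 1, 3, 5 and 7).

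The stress response to gemfibrozil 1000 µM on day 1 came from plates 1 and 5. The stress score was 1.78 and 2.04 on these plates in monoculture and 1.76 and 2.10 in co-culture, against 0.18 and 0.15 on plates 3 and 7 in monoculture and 0.36 and -0.22 in co-culture. Herpud1, which serves protein quality control in the endoplasmic reticulum, rose by 2.43 ± 0.52 and 2.75 ± 0.53 and Atf4 by 1.37 ± 0.33 in monoculture (edgeR adjusted p 0.00492, 0.00236 and 0.0113). Of stress genes, 9 of 26 rose (17 over the list alone, median 1.45, fry p 0.00423; 0, 5, 0 and 11 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 9 of 26 rose (13 over the list alone, median 1.22, fry p 0.00219, 14 rising with the block; 0, 4, 0 and 12 rising without plates 1, 3, 5 and 7). Actn1 changed by -2.54 ± 0.42 in monoculture and Krt8 by -2.35 ± 0.49 and -1.95 ± 0.48, and of cytoskeletal genes 7 of 27 fell (11 over the list alone, fry p 6.48e-06) in monoculture. In co-culture, 4 of 27 fell (15 over the list alone, fry p 3.15e-04, 10 falling with the block). The plasma protein genes Ahsg and Alb changed in co-culture by -1.76 ± 0.40 and -1.26 ± 0.35, and of hepatocyte functions 6 of 49 fell (9 over the list alone, fry p 3.73e-04, 10 falling with the block) there. edgeR called 383 genes in monoculture (202 higher, 181 lower, 761 with plate as a block, 0 in a 2-group fit) and 272 in co-culture (153 higher, 119 lower, 783 with the block, 103 in that fit). The fits without plates 1, 3, 5 and 7 called 3, 99, 4 and 651 and 0, 70, 1 and 344. With 1 plate left out, the monoculture calls lost were those of Krt8, Pdk4 and Cyp4a1 without plate 1, 3 or 5 (0.619) and of Herpud1 and Atf4 without plate 1 or 5 (0.267). Among co-culture calls, those lost were of Acot2 without plate 1 (0.129), of Krt8, Pdk4, Cyp4a1 and Ahsg without plate 1, 3 or 5 (0.396), of Alb without plate 1, 3, 5 or 7 (0.251) and of Herpud1 without plate 1 or 5 (0.237).

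On day 3 gemfibrozil 1000 µM raised the endoplasmic reticulum chaperone Hspa5 by 3.38 ± 0.77 in monoculture and 3.94 ± 0.81 in co-culture and Ddit3 by 2.87 ± 0.71 and 3.03 ± 0.74 (n = 5 and 4 treated, 4 vehicle, edgeR adjusted p 0.0147, 0.0101, 0.0255 and 0.0265). Of stress genes, 6 of 26 rose (20 over the list alone, median 1.52, fry p 6.89e-06, 15 rising with the block; 0, 0, 0, 10 and 5 rising without plates 1, 3, 5, 7 and 9) in monoculture. In co-culture, 7 of 26 rose (14 over the list alone, median 1.31, fry p 2.25e-04, 13 rising with the block; 0, 0, 0, 9 and 2 rising without plates 1, 3, 5, 7 and 9). On plate 7 the stress score was -0.08 and -0.24, the lowest of its group in each culture. Insig1 rose by 4.09 ± 1.07 and 5.68 ± 1.17, and the group includes plate 9, which has no vehicle library and where cholesterol synthesis genes were high with every treatment. Without plate 9 it stood at 3.03 ± 0.66 and 3.63 ± 0.70 (adjusted p 0.0279 and 0.00773). The hepatocyte regulator Hnf4a changed by -2.23 ± 0.56 and -2.81 ± 0.62 and the tubulin gene Tubb2b by -2.87 ± 0.63 and -2.58 ± 0.68. Of PPAR-alpha targets, 1 of 45 rose and 0 fell (9 and 1 over the list alone, fry p 0.579) in monoculture. For co-culture, 0 of 45 rose (1 over the list alone, fry p 0.96). edgeR called 122 genes in monoculture (725 with the block, 0 in a 2-group fit) and 145 in co-culture (520 and 0), and without plates 1, 3, 5, 7 and 9 it called 1, 8, 0, 241 and 55 and 3, 17, 1, 320 and 24. DESeq2's size factors moved the median of all genes from 0.30 to 0.43 and from 0.19 to 0.33. Leaving out 1 plate lost the monoculture calls of Hspa5, Ddit3 and Tubb2b without plate 1, 3 or 5 (0.411), of Insig1 without plate 1, 3, 5 or 7 (0.493) and of Hnf4a without plate 1, 3, 5 or 9 (0.4). Lost in co-culture were those of Hspa5 and Insig1 without plate 1, 3 or 5 (0.218), of Ddit3 and Tubb2b without plate 1, 3, 5 or 9 (0.38) and of Hnf4a without plate 1, 5 or 9 (0.233).

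On day 7 no gene passed with gemfibrozil 1000 µM (n = 4 treated in monoculture, 3 in co-culture). edgeR called 0 in both cultures, against 210 and 388 at an unadjusted p under 0.05 and 2 and 1 by DESeq2. Of PPAR-alpha targets, 0 of 46 rose (3 over the list alone, fry p 0.9) in monoculture. Their score was 2.00, 0.77, -0.19 and -0.24 on plates 1, 3, 5 and 7 in monoculture and 0.68, 0.18 and -0.20 on plates 3, 5 and 7 in co-culture.

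GW7647 and gemfibrozil were set against each other directly for the PPAR-alpha list, at doses that are not matched. On day 1 the list was higher with GW7647 1 µM than with gemfibrozil 100 µM by a median of 1.89 in monoculture and 1.91 in co-culture, with 5 and 4 of 45 members higher (31 and 33 over the list alone, fry p 1.76e-05 and 5.93e-05). Against gemfibrozil 1000 µM the medians were 1.11 and 1.08 (fry p 8.1e-04 and 0.00234). On day 3 they were 1.49 and 1.44 in monoculture (fry p 7.75e-06 and 1.36e-06) and 1.21 against 1000 µM in co-culture (0.00174). Against 100 µM in co-culture the median was 0.76 (fry p 0.136, 0.0321 with the block). Without the 2 plate 3 libraries named above, which favours a rise, it was 0.94 (fry p 0.0124). On day 7 the list did not pass in any of the 4 comparisons, with medians of 1.04 and 0.82 in monoculture and -0.52 and 0.40 in co-culture. At least 1 member was higher with GW7647 by edgeR in 7 of the 12 comparisons, and in 1, 6, 5 and 6 without plates 1, 3, 5 and 7.

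Ketoconazole at 30 µM raised sterol synthesis genes and lowered hepatocyte genes on day 1. Fdft1, the squalene synthase, rose by 1.90 ± 0.37 in monoculture and 2.14 ± 0.37 in co-culture (n = 4 per group, edgeR adjusted p 6.57e-04 and 2.38e-04). Cyp51, the demethylase that azoles inhibit, rose by 1.98 ± 0.47 and 1.69 ± 0.47, with 1 co-culture vehicle library at 28.01 CPM below the others, and Insig1 by 2.70 ± 0.62 in monoculture. Of cholesterol synthesis genes, 10 of 22 rose (14 over the list alone, median 1.86, fry p 0.00207; 11, 2, 0 and 8 rising without plates 1, 3, 5 and 7) in monoculture. In co-culture, 7 of 22 rose (11 over the list alone, median 1.11, fry p 0.0124; 4, 2, 1 and 1 rising without plates 1, 3, 5 and 7). The list score was 0.09 and -0.70 on plate 1 in monoculture and co-culture, and on the other plates from 1.26 to 1.87 and from 1.09 to 1.62. Its means of 1.25 and 0.91 lay below those at 10 µM (1.52 and 1.25). The urea cycle gene Arg1 changed by -2.85 ± 0.77 and -3.55 ± 0.79. Of hepatocyte functions, 5 of 49 fell (6 over the list alone, fry p 0.00679, 9 falling with the block) in monoculture. In co-culture, 7 of 49 fell (11 over the list alone, fry p 8.66e-04).

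Stress genes rose with ketoconazole on day 1 too. Trib3 rose by 1.97 ± 0.47 and 2.09 ± 0.47 and Ddit3 by 4.06 ± 1.02 and 4.52 ± 1.04 (edgeR adjusted p 0.00497, 0.00397, 0.00835 and 0.00542), and of stress genes 5 of 26 rose (12 over the list alone, median 1.01, fry p 0.0446, 10 rising with the block; 0, 4, 0 and 4 rising without plates 1, 3, 5 and 7) in monoculture. For co-culture, 7 of 26 rose (11 over the list alone, fry p 0.0131). The tight junction gene Cldn4 had 0 counts in monoculture vehicle wells and was at least 67-fold higher with ketoconazole, against a floor of 3 counts over the group. The proliferation marker Top2a, a DNA topoisomerase, changed by -4.54 ± 1.15 and -3.45 ± 1.07, and of cell cycle genes 4 of 26 fell (5 over the list alone, fry p 0.0796, 0.00977 with the block) in monoculture. In co-culture, 2 of 26 fell (7 over the list alone, fry p 0.0124, 5 falling with the block). Of the lymphocyte list, 1 of 2 fell (1 over the list alone, fry p 0.00212) in monoculture. edgeR called 871 genes in monoculture (467 higher, 404 lower, 1330 with plate as a block, 21 in a 2-group fit) and 482 in co-culture (187 higher, 295 lower, 904 with the block, 678 in that fit). Without plates 1, 3, 5 and 7 it called 488, 743, 40 and 486 and 115, 253, 103 and 204. Calls lost in monoculture with 1 plate left out were those of Arg1, Trib3 and Ddit3 without plate 1 or 5 (0.245), of Cyp51 without plate 3 or 5 (0.169) and of Fdft1, Insig1, Cldn4 and Top2a without plate 5 (0.316). The co-culture calls lost were those of Top2a without plate 1, 3, 5 or 7 (0.603, at -1.28 without plate 1), of Trib3 and Ddit3 without plate 1 or 5 (0.106), of Cyp51 without plate 3, 5 or 7 (0.198) and of Arg1 without plate 5 (0.0587).

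**Figure D3:**
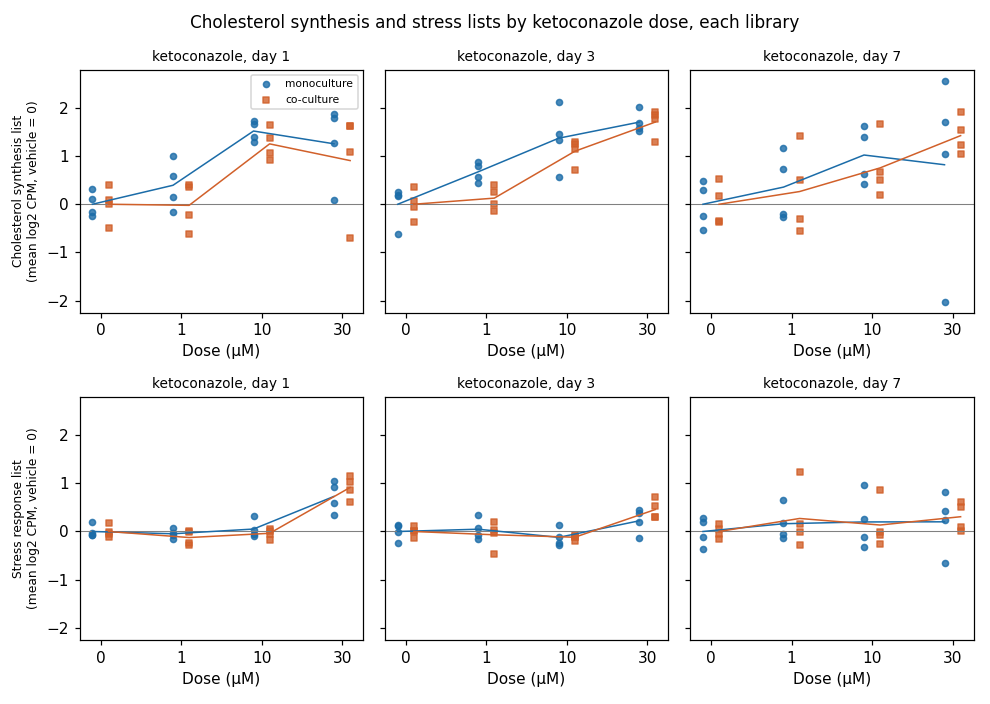
Cholesterol synthesis (upper row) and stress (lower row) scores of each library (mean log2 difference from the vehicle mean), by dose of ketoconazole, culture and day, with 1 point per library and a line through the group means. The cholesterol synthesis list median with 30 µM against vehicle on day 1 was 1.86 in monoculture and 1.11 in co-culture.

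On day 3 the cholesterol synthesis list was higher with ketoconazole 30 µM, while few single genes passed without plate as a block (n = 4 per group). Of cholesterol synthesis genes, 0 of 21 rose (11 over the list alone, median 1.72, fry p 4.98e-04, 8 rising with the block) in monoculture. In co-culture, 0 of 21 rose (12 over the list alone, median 1.31, fry p 4.99e-04, 9 rising with the block). Cyp51 stood at 2.38 ± 0.71 and 2.16 ± 0.71 and Insig1 at 3.86 ± 1.07 and 4.30 ± 1.10 (edgeR adjusted p 0.195, 0.317, 0.127 and 0.0829, and 5.17e-06, 5.17e-05, 1.4e-04 and 4.02e-05 with plate as a block). edgeR called 24 genes in monoculture (364 with the block) and 15 in co-culture (278 with the block), and without plates 1, 3, 5 and 7 it called 0, 4, 1 and 1 and 0, 2, 0 and 1.

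On day 7 the sterol genes Acat2, Cyp51 and Insig1 rose with ketoconazole 30 µM in monoculture by 3.48 ± 0.67, 2.58 ± 0.63 and 3.80 ± 1.02 (n = 4 per group, edgeR adjusted p 0.00195, 0.0165 and 0.0243). Nqo1, an antioxidant enzyme, rose by 2.90 ± 0.80. In co-culture Acat2, Cyp51 and Nqo1 stood at 2.19 ± 0.64, 1.61 ± 0.61 and 2.20 ± 0.78, each with an adjusted p of 1. Of cholesterol synthesis genes, 7 of 22 rose (13 over the list alone, median 1.67, fry p 0.212, 13 rising with the block; 5, 0, 1 and 4 rising without plates 1, 3, 5 and 7) in monoculture, where the list score was -2.02 on plate 1, in the library of 412414 counts, and 2.56, 1.03 and 1.70 on plates 3, 5 and 7. In co-culture, 0 of 22 rose (8 over the list alone, median 1.53, fry p 0.0707 and 0.00813 with the block). Of NRF2 targets, 6 of 19 rose (11 over the list alone, fry p 0.0157, 10 rising with the block) in monoculture. edgeR called 700 genes in monoculture (229 higher, 471 lower, 1626 with plate as a block) and 0 in co-culture, where 141 had an unadjusted p under 0.05, 3 passed by DESeq2 and 0 with the block. The monoculture count was 49 without the 1 library of 412414 counts and 37, 15, 21 and 706 without plates 1, 3, 5 and 7 (3, 0, 0 and 0 in co-culture). DESeq2's size factors moved the median of all genes from -0.26 to -0.41. Leaving out 1 plate lost the monoculture calls of Acat2 without plate 3 (0.104), of Cyp51 without plate 3 or 5 (0.221) and of Insig1 and Nqo1 without plate 3, 5 or 7 (0.263).

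The lower doses showed list changes more than single genes. With GW7647 0.1 µM the PPAR-alpha list was higher on day 1 in monoculture and co-culture (medians 1.07 and 1.05, fry p 0.0253 and 0.0382, 21 and 20 of 45 members higher over the list alone). With ketoconazole 10 µM cholesterol synthesis genes were higher on day 1 in both cultures (medians 1.51 and 1.41, fry p 2.53e-05 and 5.54e-04, 14 and 11 of 22 over the list alone) and on day 3 in monoculture (median 1.58, fry p 0.0058, 3 of 21). With gemfibrozil 100 µM in co-culture on day 1, hepatocyte genes and reference genes were lower (medians -0.89 and -0.84, fry p 0.0382 and 0.0382, 10 and 4 members over the list alone). Of the 48 comparisons of a lower dose with vehicle, 4 had at least 1 gene past the edgeR threshold, and 13 had it with plate as a block, among them gemfibrozil 100 µM in co-culture on day 1 with 1429 genes against 0. Leaving out plates 1, 3, 5 and 7 gave 3, 4, 0 and 2 comparisons.

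Whether a compound's response differed between the cultures was tested as the co-culture change minus the monoculture change at the highest dose. For phenobarbital, GW7647 and gemfibrozil edgeR called 0 genes on days 1, 3 and 7. The counts at an unadjusted p under 0.05 on these days were 163, 779 and 60 for phenobarbital, 373, 398 and 180 for GW7647 and 243, 359 and 80 for gemfibrozil. DESeq2 called 5, 51 and 0, 9, 34 and 0, and 4, 40 and 4. For ketoconazole edgeR called 0, 0 and 3 (383, 316 and 1423 unadjusted, 5, 41 and 18 by DESeq2). The 3 features of day 7, written LOC1009119910.00448, AABR07039694.10.028 and AABR07007905.20.0196 in the table and matching no reference symbol, differed by -8.70 ± 1.80, -11.09 ± 2.30 and -7.88 ± 1.65 (edgeR adjusted p 0.0344 each). The count was 0 without plate 1, 3, 5 or 7, with plate as a block, or without the library of 412414 counts. The PPAR-alpha list response to GW7647 differed between cultures by a median of -0.33, -0.76 and -1.14 on days 1, 3 and 7 (fry p 0.83, 0.874 and 0.991), the cholesterol list response to ketoconazole by -0.27, 0.03 and -0.14 (0.863, 0.992 and 0.8), and the stress list response to phenobarbital by 0.02, -0.03 and -0.07 (0.921, 0.982 and 0.985). DESeq2's size factors moved the median of all genes for ketoconazole on day 7 from 0.28 to 0.49.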

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

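Of the tests in this part, the 2 on the ketoconazole count of day 7 were chosen after the result was seen. Among 131 groups of 4 or 5 libraries (71 of library totals, 60 of levels of named genes), 11 held 1 library lying far from the others of its group, where chance gives about 1 in 20. Library totals stood apart in 6 of them. These were 10820668 counts in co-culture vehicle and 9274626 with ketoconazole 1 µM in monoculture on day 1, and 8915352 with GW7647 0.01 µM in co-culture on day 3. On day 7, all in monoculture, they were 6578033 with vehicle, 3126430 with GW7647 1 µM and 2192472 with gemfibrozil 10 µM.

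Gene levels stood apart in the other 5, all on day 1. In co-culture vehicle these were Cyp3a2 at 661.6, Cyp2b2 at 2.414 and Cyp51 at 28.01 CPM. With phenobarbital 10 mM in monoculture they were Ddit3 at 9369 and Cyp2b2 at 98.86 CPM.

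The response to ketoconazole 30 µM differed between cultures on day 7 for 3 probes by an edgeR test of the difference itself, and for 0 without any 1 plate, with plate as a block, or without the monoculture library of 412414 counts. Without that library the monoculture count of day 7 was 49 in place of 700, while the median of the cholesterol synthesis list was 1.996 in place of 1.667. The count was 15, 21 and 706 without plates 3, 5 and 7, which keep that library, but such fits have less power, so they cannot clear it. With the complexity covariate it was 59. On day 7 the fewest probes after thinning were 5838 on plate 1, with that library, and 9174 elsewhere.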

How the results depend on the processing

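Among the alternatives, those with the complexity covariate, without the pair of libraries under 2000000 counts and without the 2 out-of-place libraries of plate 3 were chosen after the data were seen. The others were fixed before. Of 491 counts recomputed for 46 results that answer a comparison, 286 stayed within 1.5 times the count given in the report and 205 moved further. For the lower doses 414 of 473 stayed within it and 59 did not, and for members of lists that rose or fell 636 of 1323 did and 687 did not. Of 2442 recomputed changes of named genes, 2053 kept their direction and their side of the threshold, 330 kept the direction and were no longer past it, 58 came past it, and 1 changed direction. Of 190 named changes past the threshold, 29 were smaller by more than 1 on the log2 scale without some plate. Cyp4a1 with gemfibrozil 1000 µM in co-culture on day 1 went to -1.37 ± 0.79 (edgeR adjusted p 0.396) without plate 3, the plate whose libraries carried that response, and ranged from there to 4.10 over the plates left out. Where the construction of an alternative gives no cause below, the cause was not tested.

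With the DESeq2 Wald test, the count for phenobarbital was 794 and 534 in monoculture on days 3 and 7, 747, 1393 and 41 in co-culture on days 1, 3 and 7, and 5 and 51 for the difference between cultures on days 1 and 3. On days 1, 3 and 7 GW7647 gave 34, 110 and 5 in monoculture and 51, 168 and 3 in co-culture, with 9 and 34 for the difference between cultures on days 1 and 3. The gemfibrozil count on days 1, 3 and 7 was 857, 867 and 2 in monoculture, 796, 1487 and 1 in co-culture, and 4, 40 and 4 for the difference between cultures. For ketoconazole on these days it was 1525, 181 and 1870 in monoculture, 783, 170 and 3 in co-culture, and 5, 41 and 18 for the difference between cultures. Co-culture against monoculture gave 10, 66 and 3 on days 1, 3 and 7. Day 3 against day 1 gave 850 and 1927 in monoculture and co-culture. The DESeq2 test gave more genes in each of these, and no adjusted p for up to 11399 genes. On simulated data it called 58 unchanged genes and edgeR 1, but only its fit was of 2 groups, so these do not compare. With DESeq2's size factors, the count for phenobarbital was 5 in co-culture on day 7. GW7647 gave 23 in monoculture on day 3.

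With no filter on low counts, the count for phenobarbital was 354 and 77 in monoculture on days 1 and 7 and 199 and 277 in co-culture on days 1 and 3. The gemfibrozil count on days 1 and 3 was 203 and 69 in monoculture and 161 and 47 in co-culture. For ketoconazole it was 570, 13 and 425 in monoculture on days 1, 3 and 7 and 312 and 4 in co-culture on days 1 and 3. Of the 48 lower-dose comparisons 2 had a gene past the threshold. Each of these fell, as the adjustment then covers more genes. With only the groups compared in the fit, the count for phenobarbital was 18, 1019 and 2 in monoculture on days 1, 3 and 7 and 819 and 0 in co-culture on days 3 and 7. GW7647 gave 1 in monoculture on day 3 and 4 in co-culture on day 1. Gemfibrozil gave 0 and 0 in monoculture and 103 and 0 in co-culture on days 1 and 3. For ketoconazole it was 21, 10 and 0 in monoculture on days 1, 3 and 7, 330 in co-culture on day 3, and 0 for the difference between cultures on day 7. That fit uses those groups' spread alone, widest in monoculture gemfibrozil of day 1 (median SD 0.809) and ketoconazole of day 7 (1.403). Named genes lost 61 calls and gained 6.

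With the replicate block, plate as a term, the count for phenobarbital on days 1, 3 and 7 was 927, 1124 and 668 in monoculture and 859, 2399 and 84 in co-culture. GW7647 gave 30, 26 and 1 in monoculture on days 1, 3 and 7 and 88 and 2 in co-culture on days 1 and 3. The gemfibrozil count on days 1 and 3 was 761 and 725 in monoculture and 783 and 520 in co-culture. For ketoconazole it was 1330, 364 and 1626 in monoculture on days 1, 3 and 7, 904 and 278 in co-culture on days 1 and 3, and 0 for the difference between cultures on day 7. Other values were 577 and 1625 for day 3 against day 1 in monoculture and co-culture and 13 of the 48 lower-dose comparisons with a gene past the threshold. For genes named in the report the block moved 16 to the called side and 1, Cyp4a1 with gemfibrozil in co-culture on day 1, off it, each given beside its value, and changed no other call.

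With the complexity covariate, the count for phenobarbital on days 1, 3 and 7 was 1298, 601 and 439 in monoculture and 691, 222 and 35 in co-culture. The GW7647 count was 26 and 41 in monoculture on days 1 and 3 and 45 in co-culture on day 1. For gemfibrozil it was 1205 in monoculture on day 1 and 583 and 239 in co-culture on days 1 and 3. Ketoconazole gave 1512 and 59 in monoculture on days 1 and 7, 1024 in co-culture on day 1, and 0 for the difference between cultures on day 7. The remaining values were 1125 and 1393 for day 7 against day 1 in monoculture and co-culture and 7 of the 48 lower-dose comparisons with a gene past the threshold. With libraries of at least 500000 counts, the day 7 count for phenobarbital was 267 in monoculture and 22 in co-culture. For ketoconazole it was 49 in monoculture and 0 for the difference between cultures. Without the pair of libraries under 2000000 counts, these were 338 and 26, and 98 and 0. Without the 2 out-of-place libraries of plate 3, the count for GW7647 was 2 in co-culture on day 3. The dose taken from the dose label moved neither count it applies to, and summing the probes of a symbol moved no call of a named gene.

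With each plate left out in turn, the count for phenobarbital on days 1, 3 and 7 was 104 to 447, 36 to 236 and 0 to 359 in monoculture and 52 to 190, 12 to 422 and 0 to 154 in co-culture. For GW7647 on days 1 and 3 it was 0 to 11 and 0 to 12 in monoculture and 0 to 25 and 0 to 1 in co-culture. Gemfibrozil on days 1 and 3 gave 3 to 651 and 0 to 241 in monoculture and 0 to 344 and 1 to 320 in co-culture. The ketoconazole count on days 1, 3 and 7 was 40 to 743, 0 to 4 and 15 to 706 in monoculture and 103 to 253, 0 to 2 and 0 to 3 in co-culture, and 0 for the difference between cultures on day 7. For days 3 and 7 against day 1 it was 42 to 206 and 891 to 1939 in monoculture and 159 to 1192 and 1086 to 2038 in co-culture. Other values were 0 to 4 of the 48 lower-dose comparisons with a gene past the threshold and 1 to 6 of the 12 direct comparisons with a list member higher. Each such fit has fewer libraries per group, which lowers power. Of named genes, the calls lost without plates 1, 3, 5, 7 and 9 numbered 54, 54, 81, 49 and 4.

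At 4 libraries per group edgeR called 42% of genes simulated with a change of 2 on the log2 scale, so a gene not called may have changed. The lowest totals were 412414 and 1355914 counts.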

Other observations

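Of the tests in this part, those on the cultured cells, on gemfibrozil, on the plate 3 libraries and on GW7647 over time were chosen after the result was seen, and the other splits of the libraries were planned. In vehicle monoculture, to which no non-parenchymal cells were added, mesenchymal genes rose while hepatocyte enzymes fell. In the vehicle fit, whose scaling differs from that of the fits by day, Col3a1 went from 12.1 to 2490 CPM and Lyz2 from 3.01 to 199 CPM between days 1 and 7, and of the 23 tested stellate and mesenchymal markers, of which 0 are on another list and which liver tissue also expresses, 5 averaged 10 CPM or more on day 1 and 18 on day 7. A lower hepatocyte share alone raises all other cells' markers alike. The stellate median of 5.84 exceeded that of 35 macrophage and endothelial markers (0.618) by 5.226 (bootstrap interval 3.58 to 6.832). Whether those cells changed too was not tested, so this cannot decide. A rising background would show in olfactory and vomeronasal probes, whose summed CPM changed by 0.795 on the log2 scale (8.163 ± 3.583 to 14.17 ± 4.14, SD, n = 4), far below the lower quartile of the stellate markers (4.342). With library complexity as a covariate 15 of the 23 still rose (median 6.273). A lower hepatocyte share, growth or activation of carried-over mesenchymal cells, and mesenchymal gene expression by hepatocytes losing their identity, stay open as hypotheses.

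With gemfibrozil 1000 µM on day 1 the PPAR-alpha list was high in the plate 3 libraries, the stress list in those of plates 1 and 5, and neither in those of plate 7, in both cultures. An exchange of wells with GW7647 on plate 3 would leave GW7647 wells there without a response, and their lowest PPAR-alpha score was 1.2608. The lowest total of the 8 libraries was 5199407 counts against a median of 6650391 on that day. Totals of the plate 3 libraries were 5453934 and 7302971 counts, and 4 libraries of other plates lay between them without the PPAR-alpha response, which argues against depth. With phenobarbital 10 mM on day 1 the scores of both lists differed by plate as well. The plates may have differed in the dose that reached the cells or in the cells themselves, which was not tested, and no biological explanation was tested.

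On day 3 a pair of plate 3 co-culture libraries was away from the others of its labelled doses. The library of GW7647 1 µM had a PPAR-alpha score of -0.4502 (others 1.4193 to 2.2666), and that of gemfibrozil 100 µM a stress score of 1.489 (others -0.1132 to 0.3089). A wrong label or a wrong treatment is a candidate explanation for each. The lower total, 3122054 counts, was that of the GW7647 library (median of the day 5913764.5), and whether such a depth changes the score was not tested. No biological explanation was tested.

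The 9 libraries of plate 9 had cholesterol synthesis scores of 1.85 to 2.30 (mean 1.98, SD 0.151), and the other 45 day 3 libraries of GW7647 and gemfibrozil -0.53 to 0.99 (mean 0.192, SD 0.354), and with no vehicle library on plate 9 this has no control. For GW7647 1 µM, day 7 against day 1, the standard errors of PPAR-alpha targets in monoculture were 1.234 times as large at the median, and the mean response of the list changed by -0.499 ± 0.732 in monoculture and -0.96 ± 0.46 in co-culture.

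Other splits of the same libraries were tested by limma-trend, with 35 splits, or 100 drawn where there are more. For 18 comparisons 1 split of 35, the real one, gave as many genes. Of the 29 comparisons with 35 splits, 0.83 would do so by chance. Since residuals correlated within plates, this does not exclude chance. Each of the 18 has 7 other splits that part as many plates as the real one, which gave 0 genes and are too few for a share under 0.05 within plates. For phenobarbital on days 1 and 3 the real split gave 48 and 1068 in monoculture (highest other 2 and 1) and 387 and 1014 in co-culture (highest other 4 and 6). GW7647 gave 15 and 8 in monoculture on days 1 and 3 (highest other 4 and 3) and 7 in co-culture on day 1 (highest other 3). Gemfibrozil gave 113 and 3 in co-culture on days 1 and 3 (highest other 4 and 1). Ketoconazole gave 87, 11 and 5 in monoculture on days 1, 3 and 7 (highest other 2, 1 and 0) and 706 and 376 in co-culture on days 1 and 3 (highest other 2 and 2). Time against day 1 gave 250 for day 3 in monoculture (highest other 2), 3167 for day 7 in monoculture (highest other 2045), 1577 for day 3 in co-culture (highest other 2) and 2609 for day 7 in co-culture (highest other 1). Where limma-trend gave 0 genes for the real split, each of the 35 or 100 splits gives as many by construction, and this says nothing about chance. That holds for gemfibrozil in monoculture on days 1 and 3 (highest other 3 and 1), where edgeR called 383 and 122, and for GW7647 in co-culture on day 3 (2). It also holds for co-culture against monoculture on days 1, 3 and 7 (18, 4 and 1872). Of the difference between cultures the highest others were 997, 423 and 355 for phenobarbital, 50, 0 and 3364 for GW7647, 741, 3 and 5610 for gemfibrozil and 4, 34 and 16 for ketoconazole on days 1, 3 and 7, and 1717 for time. On day 7 it holds for GW7647 in monoculture and co-culture (1336 and 1583), gemfibrozil (1216 and 2829), and phenobarbital and ketoconazole in co-culture (1970 and 3406). Phenobarbital in monoculture on day 7 gave 3 genes and 2 of 35 splits gave as many, so chance could not be excluded, and the split of plates 1 and 5 against 3 and 7 gave 18 (with plate as a block edgeR called 668). That whole-plate split also gave the 18 of culture on day 1, and plates 1 and 3 against 5 and 7 the 1872 of day 7. Splits that call many genes point to a structure of the samples other than their groups, by plate in those cases. In all comparisons of 2 groups, the other splits parting as many plates as the real one gave 0 genes, except GW7647 in monoculture on day 7 (1336).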
